A study of Microbotryum violaceum with 21 samples.

How the data were processed

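Messenger RNA of *Microbotryum violaceum* was sequenced from haploid cultures of strains 6P (mating type a1), 6D and 4T (a2), from a mated culture and from infected flower buds of *Dianthus pavonius*. RNA was extracted with a Zymo Directzol kit and libraries were made with a CD Genomics mRNA kit, per the labels. The labels and the protocol text disagree on the temperature and time of the haploid and mated cultures, and the mated label names strain 6P for both partners where the protocol mixes opposite mating types.

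The authors deposited 2 kinds of values: a table of read counts per gene and library, made per the labels with HTSeq, and FPKM values per gene and library. The deposited FPKM values are the counts scaled to a gene length and the library total, and 14367 of 14367 genes with an implied length gave the same length in all libraries within 0.1 bases. The other deposited FPKM table equals that FPKM table within 4.6e-06. The other deposited files hold 24475 coding sequences and 79880 lines of functional annotation made with PANNZER, which covers a1 models only. FastQC 0.10.1 and HTSeq 0.10.0 are named in the authors' notes, and the aligner and the genome build are not given in the sources used here. Since the values passed as counts, reads were not needed.

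Columns were matched to samples by the letters of the sample titles. This placed 11 columns, and 10 columns with no matching letter were not used. Of the 11, 5 match a single sample and 6 only a group, because several titles share the letter. These 6 are the libraries without a replicate number, and which sample or samples they hold is not known. Groups were haploid a1 (2 libraries), haploid a2 (4), mated (1) and buds (4, of classes special, other and 18-20). Lone libraries were assumed to vary like the replicated groups. Library totals were 3871831 to 43620024 counts, so values near 1 FPKM are less precise in buds than in cultures. The 10 most abundant genes took 3.46 to 5.69% of a library's counts.

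The count table holds 15038 gene IDs against 14733 a1 and 5139 a2 gene models. Of these IDs 9899 belong to an a1 model only, 305 to an a2 model only, and 4834 are used for an a1 and an unrelated a2 model, whose counts cannot be separated. Descriptions were used for the 2766 unshared a1 IDs that have one. Contigs of the assemblies were paired with BLAST+ 2.17.0 by reciprocal best matches at an e-value of 1e-20 over at least 0.8 of both sequences, which gave 695 pairs, and contigs with at least 100 pairs were used.

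Gene IDs with at least 1 FPKM in at least 2 libraries of a fit were tested. Counts were scaled by trimmed mean of M-values and compared with edgeR 4.0.16's robust quasi-likelihood test in R 4.3.3, with p-values adjusted by Benjamini and Hochberg over all tested IDs. A gene was called at an adjusted p under 0.05 and an absolute log2 difference of at least 1. The plan made before the data were examined assumed FPKM values with limma unless counts were found, and counts were found. Comparisons were a1 with a2 haploid cells, the strain pairs, mated with haploid cells, buds with mated and with haploid cells, special buds with each other class, and, as fold differences without a test among genes of at least 10 FPKM, 18-20 with other buds. Each strain and bud class had its own mean. In the fits of buds alone the spread comes therefore from the special pair, and without the libraries labelled 4T replicate 1 and 6P replicate 1 that of the haploid and mated libraries comes from the 6D pair. Standard errors are the log2 difference divided by the root of the F statistic.

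The plan also fixed 21 gene lists from descriptions. Lists with at least 5 tested members were compared with all other genes by camera in limma 3.58.1 at a preset correlation of 0.01 and at an estimated correlation, and with fry, which tests whether a set's genes move on balance one way and not against other genes. Lists were also adjusted over their own members alone.

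Genes named in the text follow a rule fixed in the plan. It takes every tested homeodomain and pheromone gene, and the 6 genes called higher and 6 called lower with the largest differences, among those described, with a mean of at least 10 FPKM on the higher side and with no overlap between libraries of the groups (3 and 3 for the smaller comparisons). It adds up to 3 members, by lowest p, of each list that passed or is described. Genes with 0 counts on a side are given against a floor of 3 counts over the group, and genes with a library of 3 counts or fewer on the lower side as a ratio of pooled counts after depth with its exact 95% interval. Shares of counts carry Wilson 95% intervals. Both kinds of interval cover counting error only, not the spread between libraries.

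Alternatives were limma on log2(FPKM + 1) and log2(FPKM + 0.1), voom with sample weights, DESeq2 1.42.0, median-ratio scaling, quantile normalization, no filter and a stricter filter, no minimum difference, only the compared libraries, and leaving out each library in turn. Testing only unshared IDs, giving shared IDs the description of their a1 model, leaving out both haploid libraries that go against their label, alone, with a filter of 1 FPKM in 1 library or with camera's estimated correlation, and the form of the planned replicate block (replicate 1 of each haploid strain against its later replicate) were added after the data were seen. Each comparison was tested on simulated data with 200 changed genes at log2 differences of 1.5 and 3 and a dispersion of 0.0189. The share of the smaller and larger changes called was 97 and 100% for a1 against a2, 93 and 98% for mated against haploid, 89 and 99% for buds against mated, 97 and 99% for buds against haploid and 84 and 90% for special against other buds. Of the unchanged genes 0, 3, 2, 7 and 2 were called, and 0 calls had the wrong direction. The simulated shares hold only for a dispersion of 0.0189, which was used for every comparison. The real fits with haploid libraries also hold both libraries that go against their label, so the simulated shares do not measure power there. With all libraries under their labels, edgeR called 0 of 9579 gene IDs for a1 against a2. Tables were handled in Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, and figures drawn with matplotlib 3.10.9.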

Results

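Messenger RNA was sequenced from *Microbotryum violaceum*, the anther-smut fungus of the pink *Dianthus pavonius*, at 3 stages of its life. Haploid cells grew on potato dextrose agar, a mated culture grew on water agar, and diseased flower buds came from infected plants. The labels list 21 samples. Among them are 9 haploid cultures of 3 strains, with 3 samples each of 6P (mating type a1), 6D (a2) and 4T (a2). The others are 3 mated cultures and 9 bud samples, of which 2 are labelled 18-20, 3 special and 4 other. The labels do not say what special and other stand for, and they call the samples biological replicates without saying whether these were separate cultures or plants. P-values therefore measure the spread between these samples, which may be technical. Values of 11 libraries could be matched to a group, 5 of them to a single sample and 6, called unnumbered here, only to a group because several titles share their letter. They are 2 each of 6P, 6D and 4T, 1 mated, 2 special, 1 other and 1 of class 18-20. The lone mated, other and 18-20 libraries were assumed to vary like the replicated groups.

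Total counts were 34533629 to 43620024 in the haploid libraries and 24430259 in the mated library. The bud libraries held 3871831 to 8763376 counts, so low values in buds are the least precise. Between 7719 and 10700 gene IDs per library had at least 10 counts. Levels are given as fragments scaled to gene length and library depth (FPKM, mean ± SD) and fitted differences on the log2 scale (± SE). A gene was called higher or lower at an adjusted p below 0.05 and a log2 difference of at least 1. Genes are placed by contig name only, since coordinates and the genome build are not given in the sources used here.

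The haploid libraries did not all carry RNA of the mating type on their label. Contigs 80 and 84 of the a1 assembly pair with a2 contig 68 through 206 and 166 reciprocal best matches, and so hold the mating-type chromosome genes that can tell the types apart. Their genes took 7.76% of the counts in the 6P library without a replicate number but 0.25% in the library labelled 6P replicate 1. In the a2 strains they took 0.251% and 0.268% (6D) and 0.284% (4T without a number), but 7.80% in the library labelled 4T replicate 1. Genes of a2 contig 68 went the opposite way, with 0.478% in the library labelled 6P replicate 1 and 0.04% in that labelled 4T replicate 1. The other 6P library gave them 0.035%, the other 4T library 0.51%, and both 6D libraries 0.503% and 0.457%. The mated library gave 5.40% to the a1 contigs and 0.294% to the a2 contig, and the 4 bud libraries gave 3.83 to 4.04% and 0.278 to 0.299%. The widest Wilson 95% interval of these shares ran from 3.84 to 3.88%, in the 18-20 library, and covers counting error only. Across gene IDs, which are not independent replicates, the library labelled 4T replicate 1 correlated with the unnumbered 6P library at Pearson's r = 0.996 and with the other 4T library at 0.843. All libraries were kept under their labels, and the number of genes called in each comparison with haploid libraries, and in the lists described, is also given without the library labelled 4T replicate 1 and the library labelled 6P replicate 1. That alternative was chosen after the data were seen.

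**Figure D1:**
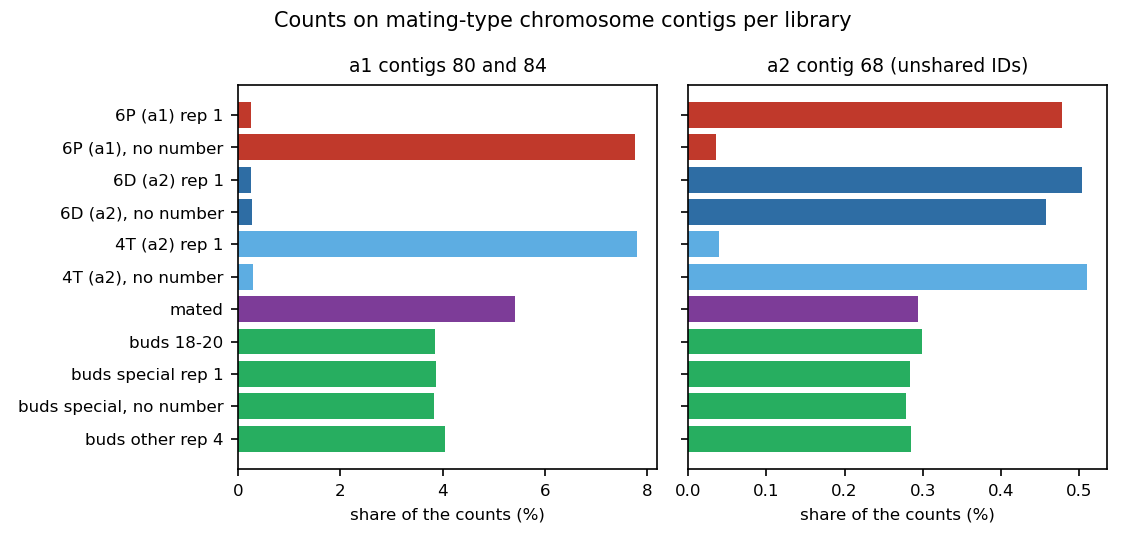
Share of each library's counts (%, bars) on a1 contigs 80 and 84 (left) and on the unshared gene IDs of a2 contig 68 (right), for 11 libraries coloured by group. The library labelled 4T replicate 1 (7.80%) sits with the unnumbered 6P library (7.76%), and the library labelled 6P replicate 1 (0.25%) with the a2 libraries.

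The copies of 11 genes on contigs 80 and 84 could be counted separately from their a2 alleles where the copies differ in sequence, with at least 100 counts per pair in every library. These pairs were chosen after the data were seen. As a median over pairs, mated cells and buds expressed both alleles: the a1 share was 49.4% in the mated library (range over pairs 26.5 to 77.8%) and 42.4 to 47.8% in the 4 bud libraries (0.0 to 71.7%). It was 0.2% in 4 haploid libraries (both 6D, the unnumbered 4T and the library labelled 6P replicate 1) and 99.7% and 99.9% in the unnumbered 6P library and the library labelled 4T replicate 1. Single pairs departed from this, with shares up to 97.2% in the former and down to 56.1% in the latter.

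**Figure D2:**
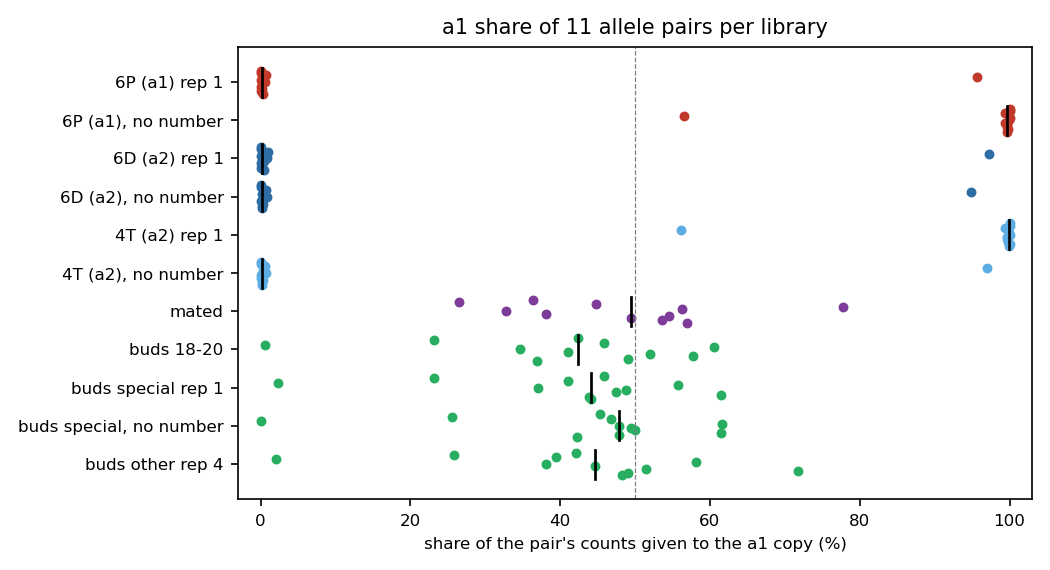
Share of each allele pair's counts given to the a1 copy (%, points; black bars are medians over 11 pairs) in 11 libraries, with a dashed line at 50%. Haploid medians are 0.2% or at least 99.7%, and those of the mated and bud libraries run from 42.4 to 49.4%.

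The comparison of a1 (6P, n = 2) with a2 haploid cells (6D and 4T, n = 4) asks which genes differ between the mating types before they meet. Only 1 a1 strain was sequenced, so mating type and strain cannot be told apart. With libraries under their labels no gene passed. The homeobox gene g8437 is described only by its homeobox domain and lies outside contigs 80 and 84, so whether it is a mating-type gene is not known. It lay at 22.4 ± 5.91 FPKM in libraries labelled a1 and 19.3 ± 8.12 in those labelled a2 (log2 difference 0.32 ± 0.24). The pheromone transporter g470 lay at 1.58 ± 0.299 and 2.12 ± 1.02 FPKM by label (-0.31 ± 0.38). Grouped by the mating type of their allele shares, after the data were seen, the libraries did not overlap for g470. It stood at 1.365 FPKM in the unnumbered 6P library and 1.128 in that labelled 4T replicate 1, against 1.619 to 3.486 in the other haploid libraries. For g8437 they overlapped (26.55 and 20.17 against 12.58 to 30.46 FPKM). This grouping was not tested. edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 of 9579 gene IDs, with 16 at an unadjusted p under 0.05, while limma called 0 and DESeq2 called 4 (3 higher and 1 lower). Without the libraries labelled 4T replicate 1 and 6P replicate 1 the same test called 166 higher and 1164 lower of 8118. The a1 side is then 1 library, and the spread comes from the 6D pair alone, with 1 residual degree of freedom. The filter limits the higher calls, since with 1 a1 library left a gene expressed in a1 alone cannot reach 1 FPKM in 2 libraries. Most of the lower calls were IDs shared by unrelated a1 and a2 models. With 1 FPKM in 1 library required instead, also chosen after the data were seen, 1664 were higher and 1236 lower of 9876.

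The genes named next were chosen by the rule used elsewhere, after the data were seen, from the alternative with 1 FPKM in 2 libraries. They therefore leave out genes such as malate dehydrogenase g3099, which reached 583.9 FPKM in the remaining a1 library and at most 0.05912 in the 3 a2 libraries of this fit. The remaining a1 library expressed g2078, an RTA1-like membrane protein, at 335 FPKM against 0.861 ± 0.243 in 3 a2 libraries (8.67 ± 0.30). The NADH dehydrogenase subunit g2931, part of respiratory complex I, was higher by 8.12 ± 0.23, the thiamine transporter g2050 by 7.51 ± 0.21 and the ribosomal protein S9 gene g5001 by 7.22 ± 0.18. The Transformer-2 homologue g2425 (7.22 ± 0.19) and the cytosine deaminase fusion gene g5015 (7.21 ± 0.21) were higher too. Of these, g2078, g2050, g5001 and g2425 have a2 copies of 99 to 99.6% identity, so the differences set 1 allele against none rather than a gene against silence. Over both copies, g2050 had fewer counts in the a1 library (11479) than in the a2 libraries (22045 to 29255). Outside these contigs, the transporter gene g473 was lower in the remaining a1 library (-3.52 ± 0.30; 1.34 against 15.9 ± 5.54 FPKM), where strain and mating type cannot be told apart. The phthalate transporter-like g490 (-2.13 ± 0.27), the carboxylic ester hydrolase g502 (-1.58 ± 0.26) and the phosphodiesterase g8535 (-1.41 ± 0.32) were also lower, as were the kinase g573 (4.06 against 12.1 ± 4.11 FPKM) and, on contig 84, the ureidoglycolate hydrolase g1846 (-1.40 ± 0.33).

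With libraries under their labels, edgeR called 0 of 1668 genes on a1 contigs 80 and 84 and a2 contig 68 and 0 of 7911 others (16 IDs at an unadjusted p under 0.05 in all), so no share could be tested. Without the libraries labelled 4T replicate 1 and 6P replicate 1, 191 of 308 of these genes were called (62.0%), against 80 of 3586 unshared IDs of other a1 contigs (2.23%). With 1 FPKM in 1 library required, 870 of 949 on contig 80 and 668 of 715 on contig 84 were higher. No test of that excess is given. The libraries were left out for their shares on these same contigs, and most genes there were read mainly in 1 mating type. Not all were: PEX14 g1830 on contig 84 stood at 114.2 FPKM in the remaining a1 library and 120.5 to 153.9 in the a2 libraries of this fit. IDs shared by unrelated a1 and a2 models were higher in 30 of 4130 and lower in 1015.

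Gene lists for a1 against a2 passed only in the fit with libraries under their labels. Transposable element genes were relatively higher (camera adjusted p = 1.98e-06), ribosomal protein genes relatively lower (0.0353), and the tricarboxylic acid cycle list relatively higher (0.0458). Each had adjusted p = 0.68 with an estimated correlation, no member was called, and none of these lists passed without the libraries labelled 4T replicate 1 and 6P replicate 1. The cycle genes malate dehydrogenase g3099 and fumarate hydratase g6281 lie on contigs 84 and 80, and their levels split the libraries of each label (g3099 at 292 ± 413 FPKM in a1 and 150 ± 300 in a2 libraries). ATP-citrate synthase g165 differed by 0.27 ± 0.12. The transposon-related genes with the lowest p, integrase g4930 (3.75 ± 1.90) and the TNT 1-94 polyproteins g3954 (5.40 ± 3.00) and g3983 (5.51 ± 3.28), lie on contig 80. Among ribosomal genes, the S10 domain gene g6451 (-0.17 ± 0.09), L4 g7510 (-0.13 ± 0.10) and L12 g428 (-0.27 ± 0.23) had the lowest p among those lower in a1, and that list had a median of -0.07 but a mean of 0.44.

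Strains were also compared in pairs. For 6D against 4T, both of type a2 by label although the library labelled 4T replicate 1 reads as a1, edgeR called 0 of 9579 gene IDs (119 at an unadjusted p under 0.05; DESeq2 called 6 higher and 360 lower, which cannot be read as a difference between strains). For 6P against 6D it called 0 (31 unadjusted; DESeq2 312 higher and 1 lower), and for 6P against 4T 0 (28 unadjusted; DESeq2 1 higher and 1 lower). limma called 0 in each. Without the libraries labelled 4T replicate 1 and 6P replicate 1, edgeR called 4 higher and 18 lower for 6D against 4T, 182 higher and 1118 lower for 6P against 6D, and 165 higher and 1170 lower for 6P against 4T, with the filter limit given above for 6P. There 6P and 4T have 1 library each and the spread is that of the 6D pair, so these counts do not measure variation within 6P or 4T.

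Mated cells (n = 1) against haploid cells (n = 6) shows what changes when the partners meet on water agar, although medium, temperature and time differ as well. The spread comes from the haploid pairs alone, so p-values say nothing of the spread among mated cultures. The 6P and 4T pairs each set a library that reads as a1 against a library that reads as a2. The pheromone transporter g470, of the class that exports lipid-modified pheromones, rose from 1.94 ± 0.848 to 21.9 FPKM (3.28 ± 0.30; edgeR adjusted p = 0.02104). The mitogen-activated protein kinase g7715 rose by 3.47 ± 0.41 (2.28 ± 0.669 to 30.5 FPKM; edgeR adjusted p = 0.02286). The G protein alpha subunit g8726, of a family that relays receptor signals, rose by 1.33 ± 0.18 (77.0 ± 12.5 to 236 FPKM). These calls and those below are fragile: g470, g7715 and g8726 kept their fold but lost their call with the replicate block and without 6D replicate 1, the unnumbered 6D, 4T replicate 1, 6P replicate 1 or the unnumbered 6P library. The count was then 0, against 434 without the unnumbered 4T library, where g470 and g7715 passed and g8726 did not. With quantile normalization g470 and g7715 did not pass either, while all 3 passed without both the libraries labelled 4T replicate 1 and 6P replicate 1. The homeobox gene g8437 did not pass (0.44 ± 0.29; 20.3 ± 7.0 and 32.6 FPKM; edgeR adjusted p = 0.4325). The chimerin-related g755, which acts on small GTPases, did not pass (0.21 ± 0.10). Of 10 tested members of the pheromone-response kinase and G protein list, 2 rose and 2 fell, as also when adjusted over the list alone. Without the libraries labelled 4T replicate 1 and 6P replicate 1, 4 rose and 2 fell, but outside contigs 80 and 84 as many rose as with all libraries. With all libraries the list did not pass (camera adjusted p = 0.793, and adjusted p = 0.865 with an estimated correlation).

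The largest increases among described genes with separate libraries included g8547, named parasitic phase-specific protein PSP-1 (5.06 ± 0.75; 134 against 3.39 ± 2.36 FPKM). The DNA-binding protein gene g424 rose by 4.67 ± 0.56, the methanol oxidase g10023, which oxidises methanol to formaldehyde, by 4.61 ± 0.38, and the carboxylesterase g10278 by 4.59 ± 0.63. The fatty acid hydroxylase g1004 rose by 4.48 ± 0.41 and the glutamate and aspartate permease g403 by 4.43 ± 0.79, to 621 from 24.1 ± 12.8 FPKM. The siderochrome-iron transporter g10064, which takes up iron bound to siderophores, fell from 84.6 ± 15.4 to 0.666 FPKM (-7.29 ± 0.62). The NADP-dependent oxidoreductase g8595 fell by 6.07 on the log2 scale (941 ± 62.6 to 17.2 FPKM) and the YRO2-related membrane protein g8849 from 4528 ± 964 to 122 FPKM (-5.52 ± 0.66). The histone gene g824 (-5.02 ± 0.56), the inactive dehydrogenase g8574 (-4.91 ± 0.48) and the dioxygenase g8850 (-4.85 ± 0.70) fell as well.

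Part of the ribosomal, respiratory and chaperone genes fell in the mated culture. Of 47 ribosomal protein genes 17 fell and none rose (29 fell when adjusted over the list alone). Among those that fell were L3 g1576 (-1.70 ± 0.21; 289 against 763 ± 62.7 FPKM), S6 g1659 (-1.55 ± 0.20) and S20 g110 (-1.28 ± 0.18). Without the libraries labelled 4T replicate 1 and 6P replicate 1, 22 fell and 5 rose, and all that rose lay on contigs 80 and 84. With all libraries the list's median log2 difference was -1.11 and camera's adjusted p = 7.08e-13, but adjusted p = 0.643 with an estimated correlation. Of 32 respiratory chain genes 16 fell (18 adjusted over the list alone), including the succinate dehydrogenase assembly factor g1539 (-3.36 ± 0.17), the succinate dehydrogenase iron-sulfur subunit g8777 (-1.87 ± 0.16) and ATP synthase subunit e g3769 (-1.79 ± 0.15). The median was -1.26, camera's adjusted p = 1.51e-12, and adjusted p = 0.405 with an estimated correlation. Chaperone genes fell in 8 of 19 (1 higher and 11 lower adjusted over the list alone), with the mitochondrial MDJ1 homologue g10349 at -2.53 ± 0.24 and the DnaJ genes g9492 at -1.86 ± 0.14 and g1171 at -1.78 ± 0.18. Camera gave this list adjusted p = 3.33e-07, and adjusted p = 0.443 with an estimated correlation.

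Of 11 tricarboxylic acid cycle genes 6 fell (6 adjusted over the list alone), among them citrate synthase g1776 (-2.07 ± 0.21) and isocitrate dehydrogenase g1596 (-2.29 ± 0.23). The list also took in 3-isopropylmalate dehydrogenase g10327 (-1.54 ± 0.13), which acts in leucine synthesis. Camera's adjusted p = 0.00349, and adjusted p = 0.405 with an estimated correlation. In the DNA replication and cell cycle list 10 of 42 fell and 3 rose (12 and 3 adjusted over the list alone). Without the libraries labelled 4T replicate 1 and 6P replicate 1, 11 fell and 11 rose of 41. Outside contigs 80 and 84, however, as many rose as with all libraries. The checkpoint gene CTF18 g10262 (-2.61 ± 0.25), the cyclin-dependent kinase regulator g1485 (-2.26 ± 0.16) and DNA polymerase g888 (-2.06 ± 0.17) fell. The list's median was -0.27 and its mean 0.19, with camera's adjusted p = 0.046, and adjusted p = 0.643 with an estimated correlation. Ribosome biogenesis had 1 lower gene of 24, the U3 small nucleolar RNA-associated UTP4 homologue g913 (-1.75 ± 0.18), and 1 adjusted over the list alone. The UTP6-domain gene g418 (-0.85 ± 0.20) and NOP53 g7284 (-1.19 ± 0.26) did not pass. Its median was -0.49 and its mean 0.08 (camera adjusted p = 0.0167, and adjusted p = 0.643 with an estimated correlation). Transposable element genes had a median of 2.09 but 2 called members of 45, the Gag-Pol polyprotein g9693 (1.08 ± 0.19) and telomerase reverse transcriptase g8825 (1.36 ± 0.17), which extends chromosome ends and is no transposon. The integrase fragment g3775 did not pass (1.38 ± 0.49). None passed adjusted over the list alone (camera adjusted p = 0.00112, and adjusted p = 0.643 with an estimated correlation).

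In all, edgeR's quasi-likelihood test called 312 gene IDs higher and 623 lower of 9717 in mated cells. Without the libraries labelled 4T replicate 1 and 6P replicate 1 it called 2516 higher and 949 lower of 9507, of which 723 and 569 of the higher ones lay on contigs 80 and 84, and 890 were called both ways. The spread is then that of the 6D pair alone, and 3 of the 4 haploid libraries left are of type a2, which gave few counts to most genes of these contigs. In that alternative 18 respiratory genes fell and 2 rose, and 9 chaperones fell and 2 rose. Of the cycle genes 6 fell and 4 rose, and of the ribosome biogenesis genes 3 fell and 5 rose. The respiratory, cycle and ribosome biogenesis genes that rose all lay on contigs 80 and 84. Camera then passed the ribosomal (adjusted p = 0.00105), respiratory (1.47e-05), chaperone (0.000272) and transposable element lists (4.35e-08), and not ribosome biogenesis (0.992), the cycle (0.948) or DNA replication (0.726). With an estimated correlation as well, none passed (camera adjusted p = 0.758 for the ribosomal, respiratory and chaperone lists and 0.842 for transposable elements). Of 39 transposable element genes 33 were then higher, but 29 of these were the 29 on contigs 80 and 84. With all libraries fry passed the respiratory, chaperone and secreted peptidase lists (fry adjusted p = 0.0168 each) and none of the others. The calls depended on which haploid libraries were used. edgeR called 0 without 6D replicate 1 (2316 at an unadjusted p under 0.05), the unnumbered 6D (2305), 4T replicate 1 (2695), 6P replicate 1 (2464) or the unnumbered 6P library (2565), and 434 without the unnumbered 4T library. It also called 0 (2524 unadjusted) with a replicate block over the haploid sets, replicate 1 against the later replicate of each strain. A replicate block was planned, and this form of it was chosen after the data were seen. With all 7 libraries limma called 1110 and DESeq2 1614. limma called more genes higher (612) than lower (498). The median log2 difference of all genes moved from 0.117 to 0.017 with median-ratio scaling and -0.098 with quantile normalization, and the medians of the passing lists kept their signs in both. With quantile normalization most were smaller: ribosomal -0.35, respiratory -0.57, cycle -0.26, chaperones -0.93 and transposable elements 0.36, with 26 of 45 positive against 41.

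Infected buds (n = 4) against mated cells (n = 1) compares growth in the plant with the first dikaryotic stage in culture. Here too p-values say nothing of the spread among mated cultures. Bud RNA came from infected plant tissue, and whether host reads were counted under conserved fungal genes was not settled. This limit holds for each comparison of buds with cultures. The aspartate aminotransferase g9018, which links amino acid and carbon metabolism, rose to 84.4 ± 3.18 from 0.550 FPKM (7.39 ± 0.50; edgeR adjusted p = 0.00162). It lies on contig 40 and has an a2 copy of 99% identity. The F-box protein gene g9851 rose by 8.57 ± 1.00 to 54.1 ± 40.8 FPKM and the LIP-domain lipase-like gene g3536 by 7.05 ± 1.88 to 291 ± 221 FPKM. The proteophosphoglycan gene g8372 had 1980 counts in buds and 1 in the mated library, a ratio of 2170 after depth (exact 95% interval 389 to 85800). The transporter g8336 had 890 and 2, a ratio of 488 (135 to 4040). The gene g1849 on contig 84 was listed at 0 in the mated library and was at least 136-fold higher in buds, with a floor of 3 counts in that library and an a2 copy of 99.9% identity. The calls of g3536, g8372, g8336 and g1849 were lost without special replicate 1 and without the unnumbered special library, and those of g3536 and g1849 with the replicate block. The call of g3536 was also lost with no filter on low values and with unshared gene IDs only.

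Several genes that were abundant in the mated culture were close to silent in buds. Where a bud library had 3 counts or fewer, fitted differences depend on the prior count, so ratios of pooled counts after depth are given with exact 95% counting intervals. The transporter g473 dropped from 834 to 0.793 ± 0.744 FPKM (39812 against 35 counts, a ratio of 1040, 746 to 1490) and lipase B g1523, which cleaves lipid esters, from 748 to 0.599 ± 0.277 (a ratio of 1310, 841 to 2180; edgeR adjusted p = 0.0007037). The ferric reductase g1170 (a ratio of 318, 193 to 569) and the siderochrome-iron transporter g10058 (174, 120 to 265), both of iron uptake, and the kinase g1503 (131, 56.1 to 406) fell too. The tyrosine recombinase g6041 on contig 80 had 574 counts in the mated library and 1 over the 4 bud libraries, a ratio of 523 (exact 95% interval 93.5 to 20700). The pheromone transporter g470 fell by 1.47 on the log2 scale to 7.06 ± 1.75 FPKM (edgeR adjusted p = 0.026), a call lost without special replicate 1 or the unnumbered special library, with quantile normalization and with limma on log2(FPKM + 0.1), and the homeobox gene g8437 did not pass (0.36 ± 0.31; 38.7 ± 5.01 FPKM in buds).

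Of 25 ribosome biogenesis genes 11 rose and none fell (11 adjusted over the list alone), with NOP53 g7284 at 1.81 ± 0.24 and the rRNA-processing gene g6546 at 1.3 ± 0.19. EFG1 g6632 (0.94 ± 0.13) passed on p but not on size. The median was 1.03 (camera adjusted p = 3.78e-06, and adjusted p = 0.439 with an estimated correlation). Of 47 ribosomal protein genes 8 rose and 1 fell (8 and 1 adjusted over the list alone) and 43 had a positive difference, among them S22 g8476 (4.16 ± 0.41; 195 ± 8.32 against 12.1 FPKM), P0 g9697 (1.61 ± 0.22) and L3 g1576 (1.21 ± 0.18). The median was 0.73 (camera adjusted p = 1.88e-08, and adjusted p = 0.439 with an estimated correlation). In the DNA replication and cell cycle list 9 of 42 rose and 4 fell (10 and 4 adjusted over the list alone). Cdc2 g8034, the kinase that drives cells into mitosis, rose by 4.01 ± 0.26 (123 ± 37.2 against 8.78 FPKM). The kinase regulator g1485 rose by 3.6 ± 0.14 and DNA polymerase g888 by 2.15 ± 0.16. Camera's adjusted p = 0.0167, and adjusted p = 0.448 with an estimated correlation. Chaperones had 3 higher genes of 19 (3 adjusted over the list alone), such as g9492 (1.44 ± 0.15), while the HSP90 kinase-targeting subunit g3584 (0.94 ± 0.09) and g10349 (0.98 ± 0.20) fell short in size, with camera's adjusted p = 0.0167, and adjusted p = 0.439 with an estimated correlation.

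Among 13 genes for plant cell wall and sugar polymer hydrolases 5 rose and none fell (5 adjusted over the list alone), but the list did not pass with camera (adjusted p = 0.0828, and adjusted p = 0.439 with an estimated correlation) and passed with fry (adjusted p = 0.0455). The pectin methylesterase g10015, which removes methyl groups from pectin, rose by 4.89 ± 0.53 (43.5 ± 34.5 against 1.41 FPKM), and the endo-polygalacturonase g8362, which cuts the pectin backbone, by 6.43 ± 1.10 (23.8 ± 14.7 against 0.186). The family 28 glycoside hydrolase g9228 was listed at 0 in the mated library and at least 303-fold higher in buds (floor of 3 counts). It lies on contig 40 with an a2 copy of 99.9% identity, so reads may be divided between copies. In the fatty acid oxidation and peroxisome list 5 of 17 fell and 1 rose (5 and 1 adjusted over the list alone), with the peroxin g9313 at -4.19 ± 0.36 and 2-enoyl-CoA hydratase g3487 at -1.61 ± 0.17 and PEX14 g1830 on contig 84, which docks proteins entering the peroxisome, from 75.0 to 30.7 ± 6.41 FPKM (camera adjusted p = 0.134, and adjusted p = 0.439 with an estimated correlation). This list passed with fry, as did the ribosomal, ribosome biogenesis and oxidative stress lists (fry adjusted p = 0.0455 each), while the cell cycle (0.23) and chaperone (0.0518) lists did not.

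edgeR's quasi-likelihood test called 805 gene IDs higher and 1052 lower of 10291 in buds against mated cells. Without the libraries labelled 4T replicate 1 and 6P replicate 1, which enter this fit through the shared spread, it called 1347 higher and 2388 lower, and with bud and mated libraries alone 1320 and 1773. In the former, 13 ribosome biogenesis genes rose and none fell, 9 ribosomal genes rose and 1 fell, 10 cell cycle genes rose and 7 fell, 3 chaperones rose, 6 cell wall hydrolases rose and 2 fell, and 1 peroxisome gene rose and 6 fell. The median log2 difference of all genes was -0.178, against -0.002 with quantile normalization, under which more genes were higher (1166) than lower (885).

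Infected buds (n = 4) against haploid cells (n = 6) compares growth in the plant with free-living cells, although mating state and growth conditions differ as well. Mating and growth in the plant cannot be told apart in this contrast. The kinase g6647, described below, stood higher in the mated culture (62.08 FPKM) than in any bud library (at most 31.71). The oxoglutarate/iron-dependent oxygenase g10031 reached 716 ± 255 FPKM in buds against 3.63 ± 1.16 (7.49 ± 0.29; edgeR adjusted p = 9.444e-05). Pooled counts are again used where a library of the lower side had 3 counts or fewer. Their exact 95% intervals cover counting error only, not the spread between libraries. The peptide transporter g9750 rose to 38.3 ± 4.84 from 0.0250 ± 0.0215 FPKM (a ratio of 1570, 1110 to 2300) and the LIP-domain gene g3536 by a ratio of 1080 (891 to 1330). The chitin deacetylase g1852 on contig 84, of enzymes that turn chitin into chitosan, rose to 53.3 ± 30.2 from 0.189 ± 0.151 FPKM (2394 against 84 counts, a ratio of 312). Between bud libraries g3536 ran from 13.78 to 474.9 FPKM and g1852 from 8.106 to 69.53. The contig 84 gene g1849 rose by a ratio of 203 (130 to 336), and the proteophosphoglycan gene g8372 had 1980 counts in buds and 1 in the haploid libraries, a ratio of 21700 (exact 95% interval 3880 to 856000). Of the hydrolase genes, the pectin methylesterase g10015 was higher by 7.21 ± 0.26 (edgeR adjusted p = 7.656e-05), g8362 by 5.76 ± 0.47, and g9228 by a ratio of 216 (159 to 302).

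Lipase B g1523 fell to 0.599 ± 0.277 from 828 ± 180 FPKM (a ratio of 1440, 921 to 2390; edgeR adjusted p = 8.328e-05). The neighbouring IDs g7774 and g7775, both glucose/galactose transporters, fell from 85.9 ± 41.9 and 107 ± 53.7 FPKM (ratios of 208, 124 to 381, and 213, 133 to 365). The siderochrome-iron transporters g10064 (a ratio of 164, 112 to 248) and g10058 (159, 109 to 241) and the kinase g1503 (107, 46 to 331) fell as well. The pheromone transporter g470 stayed above its haploid level (1.82 ± 0.20; edgeR adjusted p = 0.001322). The homeobox gene g8437 had edgeR adjusted p = 0.01401 with a difference of 0.81 ± 0.17, below the minimum size.

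Of 32 respiratory chain genes 18 fell and 1 rose (18 and 1 adjusted over the list alone), with the succinate dehydrogenase genes g1539 at -1.87 ± 0.08 and g8777 at -1.82 ± 0.08 (157 ± 9.97 against 507 ± 46.9 FPKM) and ATP synthase subunit e g3769 at -1.58 ± 0.07. The median was -1.19 (camera adjusted p = 1.24e-06, and adjusted p = 0.347 with an estimated correlation). Chaperones fell in 8 of 19 and rose in 1 (8 and 1 adjusted over the list alone), including HSP90 g9980, which folds kinases and receptors (-2.33 ± 0.15; 665 ± 50.9 against 2983 ± 384 FPKM), g1171 (-1.57 ± 0.08) and g10349 (-1.54 ± 0.12). Camera's adjusted p = 0.0202, and adjusted p = 0.462 with an estimated correlation. Ribosome biogenesis genes had a positive difference in 23 of 25, of which 2 were called higher, and 1 gene was called lower (2 and 1 adjusted over the list alone). The U3-associated UTP25 homologue g9040, on contig 40 with an a2 copy of 99.2% identity, rose by 4.20 ± 0.31, while Utp14 g3507 (0.98 ± 0.12) and EFG1 g6632 (0.67 ± 0.07) fell short in size (camera adjusted p = 0.00386, and adjusted p = 0.462 with an estimated correlation). Ribosomal proteins had a median of -0.32 but a mean of 0.05, and 0.17 as the median with quantile normalization. Of 47, 2 fell and 1 rose (2 and 1 adjusted over the list alone), with the S10 domain gene g6451 at -1.31 ± 0.08 and S0 g8631 (-0.93 ± 0.12) and S13 g1658 (-0.61 ± 0.08) short in size (camera adjusted p = 0.01, and adjusted p = 0.643 with an estimated correlation).

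Individual signalling, transport and hydrolase genes were higher in buds. Their lists did not pass with camera but passed with fry (fry adjusted p = 0.0044 for signalling, 0.000762 for hydrolases and 0.0215 for transporters). Of 11 pheromone-response kinase and G protein genes 2 rose and none fell (2 adjusted over the list alone). The STE11/CDC15 family kinase g6647 rose by 3.61 ± 0.19 (19.0 ± 13.1 against 0.742 ± 0.121 FPKM) and the mitogen-activated protein kinase g7715 by 4.38 ± 0.24 (52.1 ± 2.17 against 2.28 ± 0.669). Both entered the list by their descriptions, and that of g6647 names STE11 and CDC15 alike. Whether they act in the pheromone response is not known. The signalling list did not pass with camera (camera adjusted p = 0.13, and adjusted p = 0.462 with an estimated correlation). Of 13 plant cell wall hydrolase genes 6 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.051, and adjusted p = 0.347 with an estimated correlation). Of 22 sugar and major facilitator transporters 7 rose and 5 fell (7 and 5 adjusted over the list alone), with g1687 at 2.61 ± 0.26 and g9768 at 1.49 ± 0.07 and g1570 short in size at 0.78 ± 0.08 (camera adjusted p = 0.132, and adjusted p = 0.462 with an estimated correlation).

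edgeR's quasi-likelihood test called 1069 gene IDs higher and 1531 lower of 10291 in buds against haploid cells. Without the libraries labelled 4T replicate 1 and 6P replicate 1 it called 2460 higher and 1837 lower, including 604 higher on contig 80 and 464 on contig 84. Respiratory genes then fell in 18 and rose in 3, chaperones fell in 6 and rose in 2, and ribosome biogenesis genes rose in 10 and fell in 1. Ribosomal proteins rose in 6 and fell in 1, the opposite balance. Signalling genes rose in 4, hydrolases rose in 7 and fell in 1, and transporters rose in 8 and fell in 5. Part of the rises may come from contigs 80 and 84, since most haploid libraries left are of type a2 and gave few counts to most genes there. In mated against haploid cells, the ribosomal, ribosome biogenesis and signalling lists had 5, 5 and 2 tested members there. In that alternative the respiratory (camera adjusted p = 5.89e-05) and ribosome biogenesis lists (0.000203) passed, and the ribosomal and chaperone lists did not (both 0.0909). With an estimated correlation as well, neither passed (camera adjusted p = 0.395 for both). limma on log2(FPKM + 1) called 53.3% of its 2445 genes higher.

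**Figure D3:**
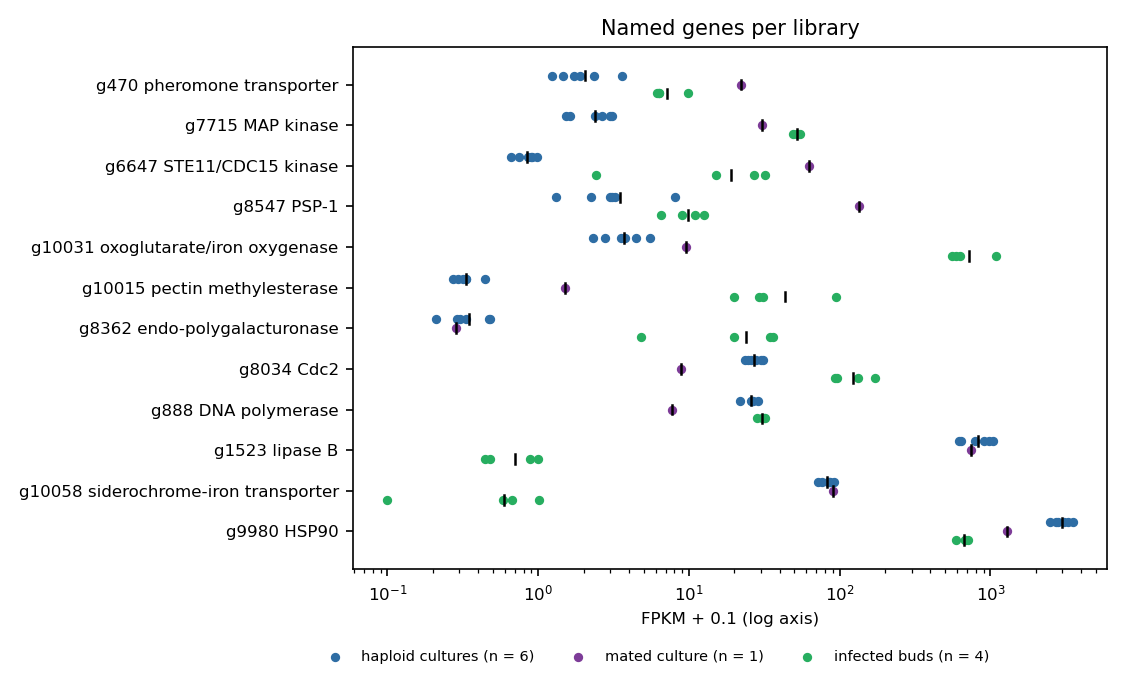
Expression of 12 named genes (FPKM + 0.1, log axis) in each haploid (n = 6), mated (n = 1) and bud library (n = 4). Points are libraries and black bars are group means. The pheromone transporter g470 is highest in the mated culture, pectin genes g10015 and g8362 in buds, and lipase B g1523 is near 0.6 FPKM in buds.

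Buds labelled special (n = 2) against the lone other bud library share the host tissue and differ in class only, as far as the labels tell. The test has 1 residual degree of freedom, from the special pair, and says nothing of the spread among other buds, so calls are given here without p-values and the differences are those between these libraries. A pair of nuclear transport factor 2 genes, g3805 and g9530, were higher in special buds by 2.75 ± 0.40 and 2.17 ± 0.36 (28.8 ± 10.7 against 4.37 and 20.9 ± 8.76 against 4.78 FPKM). Both varied elsewhere, with g9530 at 33.6 FPKM in the 18-20 library. Between haploid libraries g3805 split by replicate set. It stood at 3.34 to 4.43 FPKM in replicate 1 of each strain and at 38.6 to 92.4 in the unnumbered libraries. The cause of this split was not tested. The kinase g1427 was higher by 2.07 ± 0.31. The CFEM-domain gene g8539, of a class of cysteine-rich secreted or surface proteins, was lower (-2.04 ± 0.11; 84.6 ± 1.80 against 356 FPKM). Contig 40 genes were prominent: the copper chaperone SCO1 homologue g9198 (3.21 ± 0.26), the SGL-domain gene g9271 (3.06 ± 0.25) and the TAF4-domain gene g9287 (1.90 ± 0.35) were higher. Adenosine kinase g9311 (-4.13 ± 0.26), the TAF9 homologue g9288 (a ratio of 8.55, 5.71 to 13.3), the alginate lyase g9024 (-2.65 ± 0.33), the RNA-binding gene g9278 (-2.19 ± 0.29) and proteasome subunit N10 g9279 (-2.18 ± 0.25) were lower. Of the genes named so far g3805, g9530, g1427, g9287, g9288, g9024 and g9278 lost their call with quantile normalization, all but g3805 also with limma on log2(FPKM + 0.1), g9530, g9287 and g9288 also with limma on log2(FPKM + 1), and g9288 also with DESeq2. All of the contig 40 genes except g9278 have an a2 copy of 100% identity, to which reads can go instead, so their values are uncertain. The pheromone transporter g470 (-0.62 ± 0.20) and the homeobox gene g8437 (0.29 ± 0.14) were not called, nor were the peptide transporters g10308 (0.87 ± 0.10) and g8212 (0.43 ± 0.09) or the allantoate permease g391 (0.35 ± 0.10).

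edgeR's quasi-likelihood test called 125 gene IDs higher and 71 lower of 8848, 20 of them among 102 on contig 40. Its p-values rest on the spread between the pair of special libraries, and DESeq2 called 100, limma on log2(FPKM + 1) 91, limma on log2(FPKM + 0.1) 63 and quantile normalization 54. None of the gene lists passed with camera, the lowest adjusted p being 0.117 (adjusted p = 0.847 with an estimated correlation).

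For special buds against the lone 18-20 library, the test has 1 residual degree of freedom. Its p-values rest on the spread between the special pair and say nothing of the spread among 18-20 buds, so no p-value is given for single genes. The LIP-domain gene g3536 stood at 468 ± 9.27 against 13.8 FPKM (5.0 ± 0.13), the phthalate transporter-like g491 at 29.9 ± 0.254 against 1.06 (4.72 ± 0.38) and the kinase g1427 at 21 ± 4.30 against 0.747 (4.70 ± 0.47). The hydroxyindole protein gene g1263 was lower (-3.53 ± 0.10; 28.2 ± 1.31 against 306 FPKM), as were the BTB-domain gene g8211 (74 against 8 counts, a ratio of 23.0, 11.1 to 55.3) and g10248, related to brefeldin A sensitivity (-3.70 ± 0.34). edgeR's quasi-likelihood test called 921 higher and 383 lower of 8848 gene IDs. Of 6 secreted peptidase genes 2 rose and 1 fell in special buds (2 and 1 adjusted over the list alone), and the list was relatively lower (camera adjusted p = 0.0134, but adjusted p = 0.806 with an estimated correlation).

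The 18-20 and other buds had 1 library each and no test was made. Of 6630 gene IDs with at least 10 FPKM in either library, 206 were at least 2-fold higher and 570 lower in the 18-20 library. The proteasome alpha subunit g3792 stood at 29.5 against 0.637 FPKM and g1263 at 306 against 18.9. The CFEM-domain gene g8539 stood at 15.8 against 356 FPKM and the phthalate transporter-like g491 at 1.06 against 32.6. Adenosine kinase g9311 (1.1 against 56.6 FPKM) and the WW-domain gene g9289 (54.5 against 5.68) lie on contig 40 with identical a2 copies.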

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

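Settings without the libraries labelled 4T replicate 1 and 6P replicate 1, with unshared gene IDs only, with shared IDs in the gene lists, and the form of the replicate block were chosen after the data were seen, and the others were planned. The cause of a change was not tested unless stated. Without those haploid libraries the number of called genes was 1330 for a1 against a2 (0 with all), 191 for the mating-type contigs (0 with all), 22 for 6D against 4T, 1300 for 6P against 6D, 1335 for 6P against 4T, 3465 for mated against haploid (935 with all), 3735 for buds against mated (1857) and 4297 for buds against haploid (2600). With 1 FPKM in 1 library required as well, which keeps genes expressed in the lone a1 library, they were 2900, 1657, 32, 2880, 2856, 3733, 3881 and 4404 in the same order. The lists that passed camera numbered 4 for mated against haploid (7 with all), 2 for buds against haploid (4) and 0 for a1 against a2 (3). With DESeq2 the calls were 4 for a1 against a2, 366 for 6D against 4T, 313 for 6P against 6D, 2 for 6P against 4T, 1614 for mated against haploid and 100 for special against other buds (196 with edgeR). With unshared IDs only, which tests fewer genes by construction, they were 558 for mated against haploid, 1003 for buds against mated, 1601 for buds against haploid, 111 for special against other buds and 721 for special against 18-20 buds (1304). With no minimum difference, which adds small changes by construction, they were 2808 for buds against mated, 4819 for buds against haploid, 1157 for special against other buds and 3720 for special against 18-20 buds. With only the compared libraries buds against mated gave 3093. Special against other buds gave 91 with limma on log2(FPKM + 1), 63 with log2(FPKM + 0.1) and 54 with quantile normalization. The 18-20 against other buds gave 1682 with the 1 FPKM filter (776), which takes in more genes by construction.

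Mated against haploid depended on the haploid libraries: leaving out each in turn gave 0 to 434 calls, with 434 without the unnumbered 4T library and 0 with edgeR without 6D replicate 1, the unnumbered 6D, 4T replicate 1, 6P replicate 1 or the unnumbered 6P library, where 2316, 2305, 2695, 2464 and 2565 IDs had an unadjusted p under 0.05. Leaving out single libraries gave 1471 to 1505 calls for buds against mated and 2216 to 2546 for buds against haploid, and the haploid comparisons kept 0 edgeR calls. With the replicate block, which sets replicate 1 of each haploid strain against its later replicate, edgeR called 0 in mated against haploid (2524 unadjusted), 1479 in buds against mated and 2349 in buds against haploid. It called 0 in the haploid comparisons, with 12 (a1 against a2), 107 (6D against 4T), 40 (6P against 6D) and 21 (6P against 4T) unadjusted.

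With an estimated correlation camera passed 0 lists in mated against haploid, buds against mated (4 with the preset correlation), buds against haploid, special against 18-20 buds (1) and a1 against a2. It also passed 0 in each of the 4 comparisons run without the libraries labelled 4T replicate 1 and 6P replicate 1 and with an estimated correlation: mated against haploid, buds against mated, buds against haploid, and a1 against a2. fry passed 3 for mated against haploid, 5 for buds against mated, 12 for buds against haploid, 0 for special against 18-20 buds and 0 for a1 against a2. Quantile normalization passed 2 for buds against haploid and 5 for a1 against a2, and shared IDs in the lists gave 2 for special against other buds (0 without) and 2 for special against 18-20 buds.

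No named gene reversed its direction in the settings run. Over all settings but leaving out libraries, the named genes of mated against haploid lost their call in 46 of 418 values and gained it in 10, and those of special against other buds lost it in 17 of 136. In mated against haploid, leaving out libraries lost the call in 176 of 228 values. In buds against mated it was lost in 10 of 64 values (5 genes), and in 8 of 411 under the other settings. No block was run for the special pair, whose 1 residual degree of freedom it would take, and nothing pairs the other bud and mated libraries. The lone 18-20, other and mated libraries were not left out, since this removes a whole class. Leaving out libraries was not run for special against other or 18-20 buds, which leaves no residual degrees of freedom, 18-20 against other buds had median-ratio scaling and the filter as its only alternatives, and the other FPKM table was not run because it equals the first within 4.6e-06. Depth limits buds most, where a total of 3871831 counts makes low values imprecise.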

Other observations

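The genes in the next 2 paragraphs, the tests of the other mating type's label and of a mixture, and both tests of the shared gene IDs were chosen after the result was seen.

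The laccase-like multicopper oxidase g8138, of a family that oxidises phenols and takes part in pigment formation in fungi, stood at 76.6 ± 38.9 FPKM in buds (n = 4) against 8.57 ± 1.10 in haploid cells (n = 6; 2.95 ± 0.11; edgeR adjusted p = 9.07e-05). It was higher in the lone 18-20 library than in special buds (134 against 62.5 ± 1.68 FPKM). The alpha-amylase g8431, which cuts starch, stood at 179 ± 39.7 FPKM in buds against 36.2 ± 4.6 in haploid cells (2.22 ± 0.08; edgeR adjusted p = 8.756e-05). The peptidase g71 stood at 91.1 ± 106 FPKM in buds against 0.641 ± 0.385 in haploid cells (6.66 ± 0.58), and at 39.9 ± 4.62 in special buds. The aspartic peptidase g8806 rose in the mated culture (53.7 against 6.33 ± 1.32 FPKM; 2.81 ± 0.22) and was lower in buds (-3.27 ± 0.44).

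Single allele pairs departed from equal shares. The transcription factor IIE beta subunit g4588, needed to start transcription, gave its a1 copy 26.5% of the pair's counts in the mated library (95% interval 25.0 to 28.2%) and 23.2 to 25.8% in the 4 bud libraries. The thiamine transporter g2050 gave its a1 copy 49.4% in the mated library (47.5 to 51.2%) and 57.7 to 71.7% in the 4 bud libraries (intervals from 54.7 to 73.6%). The pair of g3873 was an exception, with 77.8% in the mated library and 0.0 to 2.3% in the buds, and with 94.8 to 97.2% in the haploid libraries where the other pairs gave a1 copies a median of 0.2%.

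The haploid libraries split by mating-type contigs against the labels of 4T replicate 1 and 6P replicate 1. A mixture with RNA of the other type would leave intermediate allele shares, and the median a1 share was 99.9% in the library labelled 4T replicate 1. Both libraries may carry the label of the other mating type: the library labelled 6P replicate 1 had a median a1 share of 0.2%. Whether they were exchanged with each other stays open, since 2 of 22 genes that differ between 6D and 4T were nearer to the unnumbered 4T library, but that library's own deviation helped to pick those genes. No biological explanation was tested.

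In a1 against a2 without those libraries, IDs used for an a1 and an a2 model were often lower in the a1 library. On contigs 90 and 100, 9.23% of shared IDs (76 of 823) were called lower against 1.14% of unshared IDs (7 of 612; Fisher's exact p = 1.93e-12). Lower expression of these contigs as a whole would have lowered both kinds. Counts of an a1 and an a2 model summed under 1 ID may account for the excess.

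Calls between special and other buds were frequent on contig 40, at 19.6% against 1.84% of unshared IDs on other a1 contigs (Fisher's exact p = 4.43e-14). The share on a2 contig 68 lay in between. Contig 40 genes without an identical a2 partner were called in 3.28% (2 of 61) against 18 of 41 with one (Fisher's exact p = 4.63e-07). This argues against a change with bud class regardless of the copy. Over all contig 40 pairs, tested or not, a1 copies in identical pairs also had fewer counts. Their median total over all libraries was 11.5, against 1710 in diverged pairs. A part played by low counts therefore cannot be told apart from that of an identical copy. On contigs 80 and 84, 8.33% of genes with an identical partner were called (2 of 24) against 0.866% of those with a diverged partner (2 of 231; Fisher's exact p = 0.0454) and 15 of 1193 of all genes without an identical one (Fisher's exact p = 0.0423). Reads split between identical copies may explain these calls, although this rests on 2 called genes, and a difference between the bud classes in the remaining genes stays untested.

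For buds against haploid cells, 1 of 100 splits drawn from 210, the real one, gave as many as 2600 calls. The median of the other splits was 0, but a shuffled class can hold bud and haploid libraries at once, which widens its spread. The splits therefore cannot decide whether chance accounts for the count. The highest other split gave 2410. That other split set the other bud library and special replicate 1 with the library labelled 4T replicate 1 and the unnumbered 6P library. The same haploid libraries with the 18-20 and other bud libraries gave 0 calls. These splits may also differ in which libraries formed a class, so comparing them does not show what accounts for the 2410, which was not tested.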
